A study of Arabidopsis thaliana with 8 samples.

How the data were processed

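The series profiled 3 cell populations of Arabidopsis thaliana roots on 8 Affymetrix arrays: phloem sieve cells with companion cells (n = 2), cortex (n = 3) and differentiating xylem (n = 3). Per the labels' protocols, each population was marked by a green fluorescent protein line, protoplasts were made from root tips of about 1 cm taken from seedlings grown for 6 days at 22 degrees Celsius, fluorescent protoplasts were collected on a cell sorter, and biotin-labelled cRNA was made from total RNA by a 2-cycle amplification. The labels call the arrays of a population biological replicates.

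The deposited values are linear array intensities, 1 value per probe set and array, and the authors made them with MAS5, per the submitters' processing notes. The version of MAS5, its target value and any further step are not given in the sources used here. The 2% trimmed mean of the intensities ranged from 190.9 to 250.05 across arrays, so no single common target is visible in the values, and how far differences between populations in overall level were set by the scaling stays unknown. The table holds no detection calls, so no probe set was called present or absent. The files give no depth, and the number of arrays limits the precision. All 8 sample columns were used. The table lists 22810 probe sets, of which 64 control probe sets were left out of the tests and 22746 were tested.

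Probe sets were named through the platform annotation given with the series, updated through a RefSeq table of assembly TAIR10.1. Of the tested probe sets, 13513 had 1 gene, 503 had several and 8730 were not listed and stay unnamed here. A match to RefSeq was found for 13436 of them. A symbol other than the locus tag was available for 1580. No probe set with several genes was named. A probe set whose identifier ends in _s_at or _x_at (1061 of those tested) can bind transcripts of related genes. No genome coordinates are given, since the sources state no build for the array.

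Gene length was taken from the RefSeq table. Intensities were transformed as log2(value + 16) with no further normalization and fitted in R 4.3.3 with limma 3.58.1, 1 mean per population over all 8 arrays, moderated with an intensity trend. The fit had 5 residual degrees of freedom, to which the moderation added 3.66. Fold changes are on this log2(value + 16) scale and understate the change of dim probe sets. Each pair of populations was one contrast, with Benjamini-Hochberg adjustment within the contrast and a threshold of 0.05. A probe set was called enriched in a population when it passed that threshold and was at least 2-fold higher against each of the other populations. The 3 contrasts share arrays, so their calls are not independent. On simulated data with the spread of these arrays, in 22746 probe sets, 83% of 100 above-median probe sets changed 4-fold between xylem and cortex were recovered and 32% to 34% of those changed 2-fold. For phloem against cortex the values were 72% to 74% and 17% to 23%, and for xylem against phloem 74% and 18%. At most 5 unchanged probe sets were called in any of these runs. Only 100 probe sets per fold were changed in a run, far fewer than differed on the real arrays. The adjusted threshold was therefore stricter in the runs, and these shares do not measure recovery in the contrasts below.

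Gene lists, the rule for transcription factors, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The 20 lists hold 242 genes, and 30 of these had a probe set listed with 1 gene, so coverage is low. The probe set with the highest mean was taken per gene. The 5 lists with at least 3 measured genes were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation. No member was measured of the lists for xylem cell death, root cap, pericycle and stele transport, mitotic cell cycle, primary wall cellulose and aquaporins. Transcription factors were taken by fixed patterns in symbols, synonyms and full names, which matched 101 probe sets, among them a gene that is no factor, and missed factors without such a name. Matches were counted among enriched probe sets with a 2-sided Fisher's exact test. Named genes were those with a symbol: per population the 10 enriched probe sets with the largest smaller log2 fold change, brighter than the median probe set and with every array above every array of the other populations, the first 5 enriched matches to the transcription factor pattern in the same order, per pair the 5 highest and 5 lowest, and all measured list members. The first 5 genes with only a locus tag are given as well where the text says so. Plots were drawn in Python 3.11.15 with matplotlib 3.10.9.

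The arrays of different populations share replicate numbers, and whether these pair the arrays was checked on deviations from the population means across probe sets. Same-numbered arrays had r of -0.10, -0.04 and 0.15 for xylem and cortex, -0.0012 and -0.03 for phloem and cortex, and 0.13 and 0.15 for xylem and phloem. The last are only 2 pairs, and deviations of 2 phloem arrays mirror each other. Since not all of the 3 xylem and cortex pairs exceeded 0.1 and the labels name no shared batch, the arrays were not treated as paired.

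Alternatives were other pseudocounts (1 and 64), quantile normalization, median centring, only probe sets above the median intensity, no intensity trend, the replicate number as a block, fits on 2 populations, other fold minimums and leaving out each array. Scaling on the hybridisation spike-in controls or on the trimmed mean was added after seeing the data.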

Results

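Transcripts were measured in 3 sorted cell populations of the Arabidopsis root tip: phloem sieve cells with companion cells (n = 2 arrays), which carry and load sugars, cortex (n = 3), the ground tissue around the stele, and differentiating xylem (n = 3), whose cells lay down secondary walls. The stated purpose was an expression map of root cell types without overlap, to be set beside promoter fusions imaged in roots. Values below are log2(intensity + 16), with the SD over arrays, and log2 fold changes from limma with their SE. Orders by fold change hold for the added 16, which sets the fold change of genes that were dim in the population compared.

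Arrays of 1 population resembled each other more than any array of another population. Across probe sets, which are not independent replicates, Pearson's r within a population ran from 0.949 to 0.984, against 0.839 to 0.857 between phloem and cortex, 0.728 to 0.790 between phloem and xylem and 0.719 to 0.784 between cortex and xylem. The first principal component held 61.8% of the variance and set xylem apart from the rest, and the next held 27.1% and separated phloem from cortex. Xylem arrays had the lowest median intensity, 41.7 ± 0.85 (SD, n = 3), against 61.9 ± 0.53 (n = 3) in cortex and 72.0 ± 2.32 (n = 2) in phloem. In xylem the 100 brightest probe sets held 12.7% ± 1.01 of the total intensity, against 8.18% ± 0.19 in cortex and 10.03% ± 0.93 in phloem. RNA quality controls also differed: the 3'/5' ratio of the GAPDH probe sets was 1.34 ± 0.14 in cortex, 1.96 ± 0.27 in phloem and 1.99 ± 0.57 in xylem, with 2.63 in xylem replicate 2. The ubiquitin ratio ran the other way, 2.73 ± 0.08 in cortex, 2.27 ± 0.26 in phloem and 1.90 ± 0.20 in xylem. The actin ratio was 5.65 ± 0.59 in cortex, 8.06 ± 0.82 in phloem and 6.83 ± 2.48 in xylem, where replicate 2 had 9.69 against 5.26 and 5.53 in replicates 1 and 3.

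Measured genes of the phloem, cortex and secondary wall lists had their highest mean in their own population, apart from OPS (AT3G09070) and AT1G62500, which were dim in all 3. The 2 measured root hair genes, the expansins EXPA7 and EXPA18, mark a cell type that was not sorted and were highest in phloem. CLE41 (AT3G24770), a peptide signal made in phloem, stood at 10.35 ± 0.22 in phloem, 7.51 ± 0.26 in cortex and 5.20 ± 0.11 in xylem. Its intensity in cortex was 13.01% of that in phloem, and that of SWEET11 (AT3G48740), a sucrose exporter, was 4.52% in cortex and 4.38% in xylem. The cortex marker AT1G09750 stood at 11.35 ± 0.21 in cortex, with 1.64% of the cortex intensity in phloem, while the cortex marker AT5G02000 kept 12.0% in phloem and 6.97% in xylem. IRX15 (AT3G50220), which acts in xylan synthesis of secondary walls, stood at 11.83 ± 0.20 in xylem, and its mean intensities of 2.29 in cortex and 5.13 in phloem lay under the pseudocount of 16. Without detection calls, intensities near that level are not shown to exceed background, so percentages that rest on them are uncertain.

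**Figure D1:**
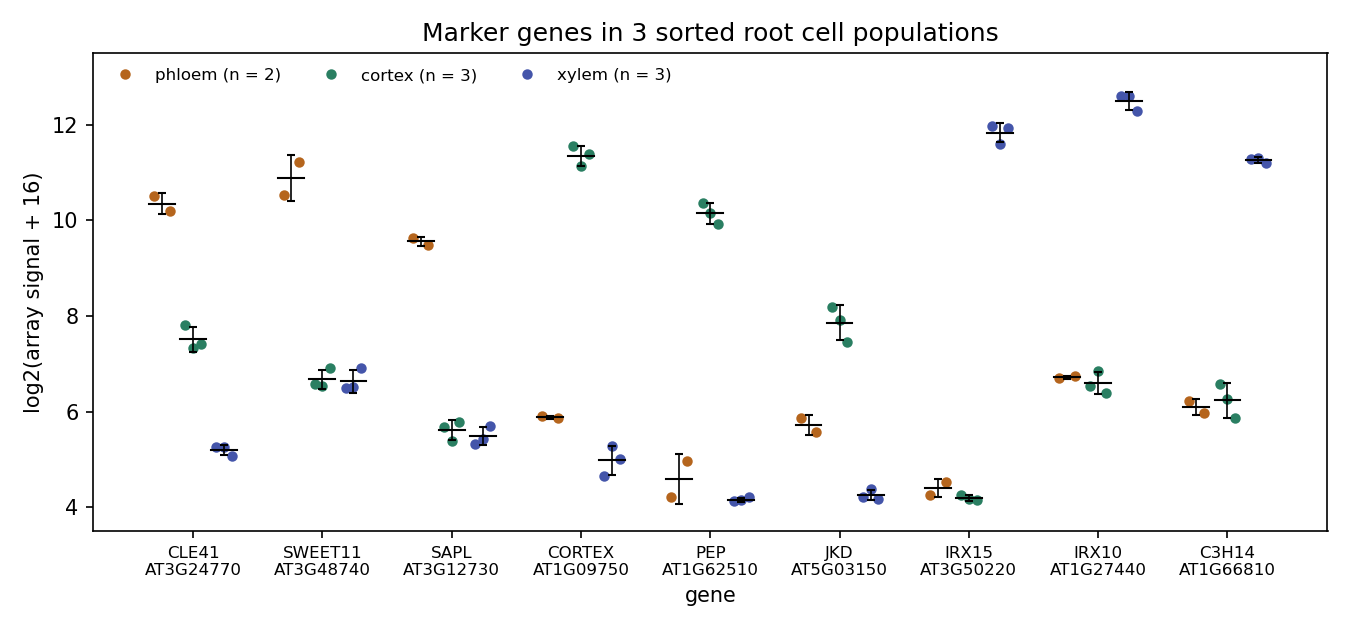
Values per array (points), mean (horizontal line) and SD (vertical bar) of log2(intensity + 16) (vertical axis) for 9 marker genes (horizontal axis) in phloem (n = 2), cortex (n = 3) and xylem (n = 3). The genes were picked from the measured list genes, without OPS and AT1G62500, which were dim and not highest in their own population. The 3 phloem genes, the 3 cortex and ground tissue genes and the 3 xylem genes shown are each highest in their own population, for example IRX15 at 11.83 in xylem against 4.19 in cortex and 4.40 in phloem.

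Xylem was first set against cortex. Secondary wall genes were far higher in xylem: IRX15 by 7.64 (SE 0.18) on the log2 scale, IRX10 (AT1G27440, listed as GUT2), a xylan xylosyltransferase, by 5.90 (SE 0.17), and IRX15-L (AT5G67210) by 4.04 (SE 0.25). The subtilase SBTI1.1 (AT1G01900) had the largest difference among genes with a symbol, 7.93 (SE 0.30), and the xylan acetyltransferase TBL34 (AT2G38320), the Aux/IAA auxin response repressor IAA29 (AT4G32280) and the carboxypeptidase-like scpl20 (AT4G12910) followed at 6.28, 6.27 and 6.20. Lowest in xylem among genes with a symbol were the glycosyltransferase UGT71C1 (AT2G29750) at -6.24 (SE 0.24), the aspartic protease NANA (AT3G12700) at -5.59 (SE 0.29) and the endoglucanase GH9B13 (AT4G02290) at -5.39 (SE 0.19). MSRB9 (AT4G21850), a methionine sulfoxide reductase, at -5.25 (SE 0.86), and GH3.3 (AT2G23170), which conjugates auxin to amino acids, at -5.20 (SE 0.32), were also low. The limma adjusted p-values of these genes were at most 0.00107, the value of MSRB9.

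Of the secondary wall and xylan list, 3 of 15 genes were measured, and all 3 were higher in xylem than in cortex, over all probe sets and adjusted over the list alone. The camera adjusted p was 4.22e-05, and adjusted p = 0.0669 with an estimated correlation. Among other xylem lists only single members were measured, and each was higher in xylem: the zinc finger regulator C3H14 (AT1G66810) by 5.03 (SE 0.20) (adjusted p = 2.32e-07), the lignin pathway enzyme HCT (AT5G48930) by 2.51 (SE 0.25) (adjusted p = 4.84e-05) and the HD-ZIP III factor PHV (AT1G30490) by 2.78 (SE 0.25) (adjusted p = 3.21e-05). The 3 measured auxin genes of 23 were all higher in xylem, also adjusted over the list alone: IAA29, IAA30 (AT3G62100) by 1.503 (SE 0.25) and IAA20 (AT2G46990) by 0.78 (SE 0.18). Their camera adjusted p was 0.00302, and adjusted p = 0.0848 with an estimated correlation. Of 4 measured cortex markers, 3 were lower in xylem, again also adjusted over the list alone: AT1G09750 at -6.37, AT1G62510 at -5.99 and AT5G02000 at -3.07. The remaining one, AT1G62500, differed by -0.20 (SE 0.27) and was dim in every population. The camera adjusted p of that list was 0.00465, and adjusted p = 0.0848 with an estimated correlation. JKD (AT5G03150), a zinc finger regulator of ground tissue, was lower in xylem at -3.60 (SE 0.23), as were both measured endodermis genes, SGN3 (AT4G20140, listed as GSO1) at -2.38 (SE 0.21) and AT1G61590 at -1.93 (SE 0.30). The root hair expansins EXPA7 (AT1G12560) and EXPA18 (AT1G62980), markers of a cell type that was not sorted, were lower in xylem than in cortex at -1.08 (SE 0.28) and -1.13 (SE 0.27). Of the 5 measured phloem genes, CLE41 was lower in xylem than in cortex at -2.31 (SE 0.19) and AT5G02460, a Dof factor also called PEAR2, at -0.68 (SE 0.18). That list as a whole had a camera adjusted p of 0.446. The calls of AT5G02460 and EXPA7 were lost under 2 alternatives, and those of EXPA18 and IAA20 under 1.

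In total 9696 of 22746 probe sets differed between xylem and cortex, 3074 higher and 6622 lower in xylem, and without xylem replicate 2 the number was 9921. The share of higher calls was 31.7% with the arrays as deposited, 48.9% after quantile normalization, 63.8% after median centring, 11.1% after spike-in scaling and 40.2% after trimmed-mean scaling, so the balance of higher and lower depends on the scaling. The median of all probe sets moved from -0.14 as deposited to 0.04, 0.29, -0.68 and -0.03 under these scalings.

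Phloem was then set against cortex. Among genes with a symbol, those highest in phloem included ATC (AT2G27550), a relative of the flowering regulators FT and TFL1, by 7.95 (SE 0.37), and the glutathione S-transferase GSTF4 (AT1G02950) by 7.74 (SE 0.25). Their order rests on the pseudocount: with a pseudocount of 1 they stood at 8.78 and 10.72, since their mean cortex intensities were 24.1 and 1.20. NTL (AT1G11570), a nuclear transport factor 2-like gene, was higher by 6.81 (SE 0.40), the calmodulin-like CML30 (AT2G15680) by 6.55 (SE 0.22) and TBL45 (AT2G30010) by 5.91 (SE 0.31). SWEET11 was higher by 4.204 (SE 0.25), CLE41 by 2.84 (SE 0.21) and CLE26 (AT1G69970), of the same peptide family, by 5.27 (SE 0.34). Lowest in phloem by the same rule were NANA at -3.74 (SE 0.33), the chalcone isomerase-like gene CHIL (AT5G05270), which acts in flavonoid synthesis, at -3.65 (SE 0.35), UGT71C1 at -3.58 (SE 0.27), GH3.3 at -3.51 (SE 0.35) and UGT84A1 (AT4G15480) at -3.35 (SE 0.50), which came to -5.97, the lowest of these, with a pseudocount of 1. The limma adjusted p-values of these 13 genes were at most 0.00133, the value of UGT84A1.

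Of 37 phloem list genes 5 were measured, and 4 were higher in phloem than in cortex, over all probe sets and adjusted over the list alone. These were SWEET11, CLE41, AT3G12730, a SAPL-type MYB-related gene, by 3.95 (SE 0.22) and AT5G02460 by 0.91 (SE 0.20). OPS differed by 0.15 (SE 0.26). The list passed with camera, adjusted p = 0.000246, and adjusted p = 0.045 with an estimated correlation. The cortex markers AT1G09750, AT1G62510 and AT5G02000 were lower in phloem at -5.47, -5.56 and -2.58, 3 of 4 measured, with the same 3 adjusted over the list alone. Their camera adjusted p was 0.00159, and adjusted p = 0.0532 with an estimated correlation. JKD at -2.14 and SGN3 at -1.77 were lower too, while the other measured endodermis gene, AT1G61590, differed by 0.70 (SE 0.34) and did not pass (adjusted p = 0.175). Of the auxin list IAA29 was higher in phloem by 2.10 (SE 0.25) and IAA20 by 0.95 (SE 0.20), while IAA30 differed by 0.37 (SE 0.28). The same 2 genes passed adjusted over the list alone, and the camera adjusted p was 0.0295, with adjusted p = 0.2 with an estimated correlation. The cytokinin response gene ARR15 (AT1G74890) was lower in phloem at -1.32 (SE 0.30), and ARR16 (AT2G40670, listed as RR16) was dim and differed by 0.25 (SE 0.17). Neither passed in the pairs with xylem. Of 3 measured secondary wall genes only IRX15-L differed, at -1.36 (SE 0.28), lower in phloem. The median of that list was 0.12 and its mean -0.35, with a camera adjusted p of 0.714. HCT was higher in phloem by 0.86 (SE 0.28), a call that was lost under 13 alternatives, and PHV by 1.12 (SE 0.28), lost under 3. EXPA7 and EXPA18 were higher in the phloem arrays, by 1.38 (SE 0.32) and 1.29 (SE 0.30). Both were also over 2-fold higher in phloem than in xylem, so these root hair genes met the rule for phloem enrichment. The stress-response zinc finger gene ZAT10 (AT1G27730, listed as STZ) differed by 0.67 (SE 0.29) and passed only over the list alone. That list had 1 measured member, so no adjustment was made there. The call of EXPA18 was lost under 2 alternatives, and those of EXPA7, ARR15, AT5G02460, IAA20 and IRX15-L under 1 each.

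A total of 6140 probe sets differed between phloem and cortex, 2781 higher and 3359 lower in phloem, and 7489 without xylem replicate 2, which enters through the shared spread. Without phloem replicate 2 the number was 3606, where 1 phloem array was left and was assumed to vary like the other populations, and after spike-in scaling it was 9895. Higher calls made up 45.3% as deposited, 33.1% after median centring and 17.78% after spike-in scaling, but 52.0% after trimmed-mean scaling and 53.3% without phloem replicate 2, so the balance turned over. The median of all probe sets moved from -0.03 as deposited to -0.20, -0.44 and 0.03 under these scalings.

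Xylem was also set against phloem, both parts of the vascular tissue. The 3 measured secondary wall genes were higher in xylem, IRX15 at 7.44 (SE 0.20), IRX10 at 5.78 (SE 0.19) and IRX15-L at 5.40 (SE 0.28), with SBTI1.1 at 6.82 (SE 0.34) and TBL34 at 5.82 (SE 0.17). On the phloem side were ATC at -7.43 (SE 0.37), GSTF4 at -7.23 (SE 0.25), NTL at -6.89 (SE 0.40), a further glutathione S-transferase, GSTU23 (AT1G78320), at -6.14 (SE 0.27) and the endoglucanase GH9B8 (AT2G32990) at -5.65 (SE 0.44). C3H14 was higher in xylem by 5.17 (SE 0.22), PHV by 1.66 (SE 0.28) and HCT by 1.65 (SE 0.28). The limma adjusted p-values of these 13 genes were at most 0.00155, the value of PHV.

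The secondary wall list was higher in xylem than in phloem in 3 of 3 measured genes, also adjusted over the list alone, with a camera adjusted p of 2.71e-05, and adjusted p = 0.0616 with an estimated correlation. The phloem list was lower in 4 of 5, with CLE41 at -5.15, SWEET11 at -4.25, AT3G12730 at -4.07 and AT5G02460 at -1.59. The same number passed adjusted over the list alone, and the camera adjusted p was 0.00475, with adjusted p = 0.0622 with an estimated correlation. In the auxin list, IAA29 was higher in xylem by 4.17 (SE 0.25) and IAA30 by 1.13 (SE 0.28) (lost under 2 alternatives), 2 of 3 also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0586). Of the cortex markers AT1G09750 was lower in xylem than in phloem at -0.91 (SE 0.22), 1 of 4 by either adjustment, a call lost under 5 alternatives (list camera adjusted p = 0.266). JKD was lower in xylem at -1.46 (SE 0.26), AT1G61590 at -2.62 (SE 0.34), EXPA7 at -2.46 (SE 0.32) and EXPA18 at -2.42 (SE 0.30). ZAT10, the only measured gene of the wound and heat list, was lower in xylem than in phloem at -0.94 (SE 0.29), a call lost under 4 alternatives. LHCB4.1 (AT5G01530), the only measured photosynthesis gene, was lower in xylem than in cortex at -1.80 (SE 0.39) and differed from phloem by -1.06 (SE 0.43) (adjusted p = 0.0792). LHCB4.1 and SGN3, which differed by -0.60 (SE 0.23), passed there only over the list alone. For LHCB4.1, the only measured member of its list, that is no adjustment.

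Between xylem and phloem 9639 probe sets differed, 3163 higher and 6476 lower in xylem, and 10204 without xylem replicate 2. Higher calls made up 32.8% as deposited, 52.1% after quantile normalization, 71.2% after median centring, 26.0% after spike-in scaling and 36.3% after trimmed-mean scaling, and the median of all probe sets moved from -0.15 to 0.08, 0.46, -0.24 and -0.10.

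**Figure D2:**
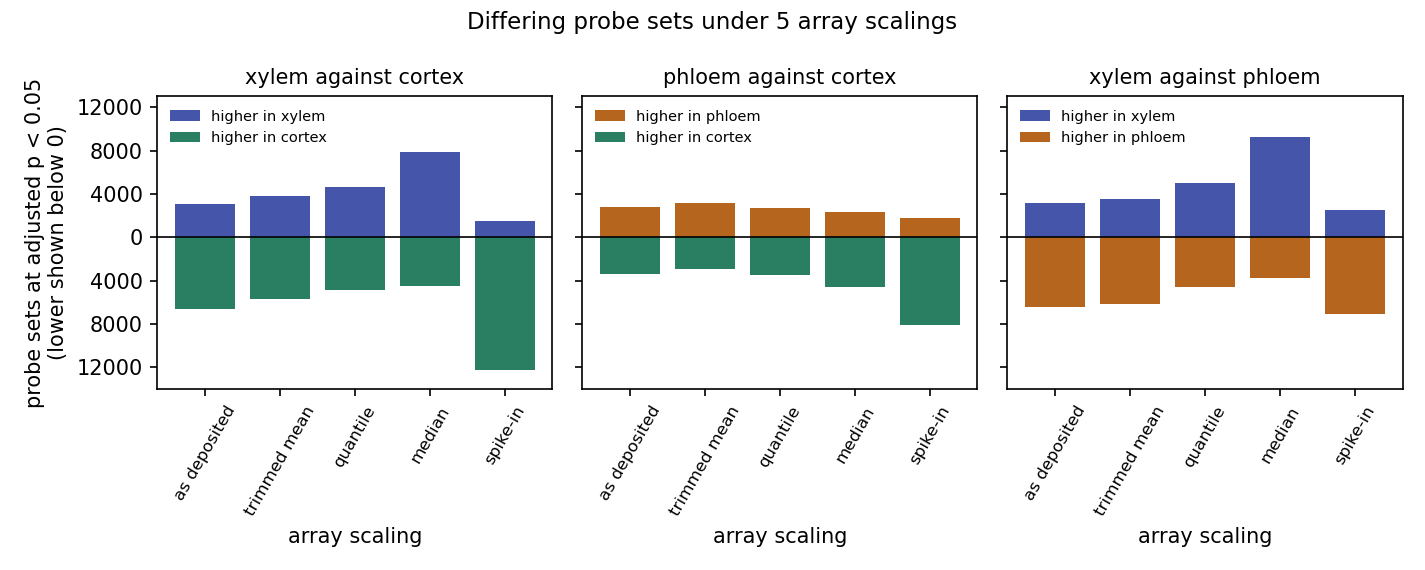
Number of probe sets past the threshold of 0.05 on adjusted p (vertical axis) in each pair of populations under 5 array scalings, higher ones above 0 and lower ones drawn below 0. For xylem against cortex, 3074 were higher and 6622 lower as deposited, while after median centring more were higher than lower.

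Of 3 measured reference genes, AT4G34270 (TIP41-like) differed by 0.01 (SE 0.16) between xylem and cortex, and AT2G28390 (MON1) by 0.09 (SE 0.16), and neither passed. Under spike-in scaling both were lower in xylem, at -0.80 and -0.73. UBC21 (AT5G25760, listed as PEX4) was higher in xylem than in cortex by 0.89 (SE 0.19), a call lost under 1 alternative, and AT2G28390 was lower in phloem than in cortex at -0.62 (SE 0.18), a call lost under 7 alternatives. Against phloem, UBC21 and AT2G28390 were higher in xylem by 0.70 (SE 0.22) and 0.71 (SE 0.18), calls lost under 6 and 2 alternatives, and the counts over all probe sets and adjusted over the list alone were equal in each pair. The reference list had camera adjusted p-values of 0.27, 0.604 and 0.0737 for xylem against cortex, phloem against cortex and xylem against phloem.

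The map was then read for probe sets enriched in 1 population over both others. In phloem 1387 probe sets were enriched, among them ATC (7.43, the smaller of its log2 fold changes), GSTF4 (7.23), NTL (6.81), GSTU23 (5.54) and GH9B8 (5.27). CLE26 (5.04), CML30 (5.02), TBL45 (5.01), the subtilase SBT4.12 (AT5G59090, 4.78) and SWEET11 (4.204) had smaller values. With a pseudocount of 1 GSTF4 (8.79) stood above ATC (7.92), and CLE26 (6.79) above GSTU23 (6.57). Larger at the added 16 were genes with only a locus tag, AT1G05770 (8.07), AT4G09950 (7.79), AT5G02140 (7.75), AT1G61760 (7.62) and AT2G27140 (7.61). The root hair expansins EXPA7 and EXPA18, from a cell type that was not sorted, were phloem-enriched as well.

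In cortex 1435 probe sets were enriched. NANA (3.74), CHIL (3.65) and GH3.3 (3.51) were joined by 4 UDP-glycosyltransferases, UGT71C1 (3.58), UGT84A1 (3.35), UGT76B1 (AT3G11340, 3.08) and UGT71B1 (AT3G21750, 2.96), by the beta-tubulins TUB5 (AT1G20010, 3.15) and TUB1 (AT1G75780, 3.15) and by the cytochrome P450 gene CYP71B34 (AT3G26300, 2.98). With a pseudocount of 1 UGT84A1 (5.97) stood above NANA (3.92). On adjusted p alone, without the 2-fold minimum, the UGT76B1 call was lost under 2 alternatives. By locus tag AT1G62510 (5.56), AT3G05150 (5.53), AT5G11420 (5.51), AT1G09750 (5.47) and AT3G21670 (4.64) led.

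In xylem 1266 probe sets were enriched, led by IRX15 (7.44), SBTI1.1 (6.82), TBL34 (5.82), IRX10 (5.78) and scpl20 (5.32). The vacuolar processing enzyme ALPHA-VPE (AT2G25940, 4.33), IAA29 (4.17), the actin ACT11 (AT3G12110, 4.102), IRX15-L (4.04) and scpl48 (AT3G45010, 3.94) came next. By locus tag AT1G70500 (7.71), AT1G24030 (7.24), AT1G05310 (7.22) and AT1G24600 (7.09) stood beside IRX15. Differences over 16-fold against both others were counted for 162 phloem, 23 cortex and 175 xylem probe sets.

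**Figure D3:**
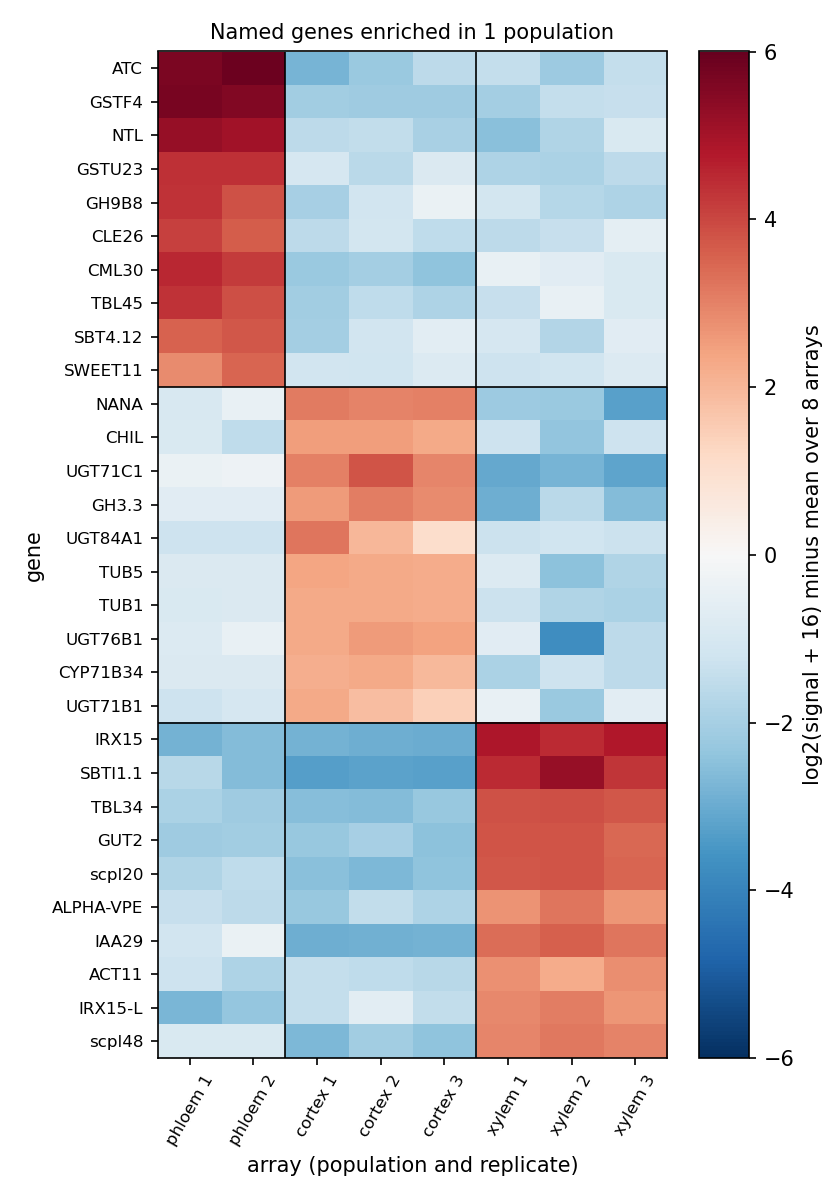
Heat map of log2(intensity + 16) minus its mean over the 8 arrays for the 10 named genes enriched in phloem (upper block), cortex (middle block) and xylem (lower block), 1 column per array. Each block is red (above the mean) in the arrays of its own population and blue or pale in the others, from IRX15 and SBTI1.1 in xylem to UGT71B1 in cortex.

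Calls against both others share the arrays of the enriched population. Independent lists of the same sizes would overlap in 451 probe sets for phloem, 442 for cortex and 174 for xylem. Simulated arrays with no difference gave at most 0 enriched probe sets with limma in 20 runs. No pair differed in those runs, so they cannot show how many calls shared arrays add where populations do differ. With 2 or 3 arrays a population has too few for 2 arrays on each side of a split, so none was made and part of the excess may come from shared arrays. After median centring 2391 probe sets were enriched in xylem, and after spike-in scaling 798 in xylem and 3870 in cortex.

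Transcription factors were the subject of the series. Genes were counted as factors by the fixed name pattern, and the order is among matches brighter than the median probe set. In phloem 8 of 762 enriched probe sets with 1 gene matched, with bZIP44 (AT1G75390, 2.80), WRKY22 (AT4G01250, 2.04), the MADS-box gene AGL18 (AT3G57390, 1.496), LBD16 (AT2G42430, 1.45), known for its part in lateral root formation, and the HD-ZIP II gene HAT2 (AT5G47370, 1.36) highest in that order. The WRKY22 call, with limma adjusted p = 0.0364 against cortex, was lost under 6 alternatives. In cortex 5 of 672 matched, of which WRKY6 (AT1G62300, 1.82), bZIP52 (AT1G06850, 1.40) and WRKY47 (AT4G01720, 1.19) have a symbol of such a family. XEG113 (AT2G35610, 1.22) met the fixed pattern only through a synonym and is an arabinosyltransferase, and AT2G21230, named after its values were seen, was the remaining one. In xylem 7 of 702 matched, with IAA29 (4.17), PHV (1.66), the trihelix factor GT-1 (AT1G13450, 1.46) and the membrane-bound factors BZIP17 (AT2G40950, 1.29) and BZIP28 (AT3G10800, 1.20), which act in the stress response of the endoplasmic reticulum, highest. The pattern missed factors of the fixed lists that were enriched and whose smaller fold change exceeded that of every match in the same population: AT3G12730 in phloem (3.95), JKD in cortex (2.14) and C3H14 in xylem (5.03). On adjusted p alone, the calls of HAT2, bZIP52, WRKY47, BZIP17 and BZIP28 were each lost under 1 alternative. Whether the named matches stayed at least 2-fold higher than both other populations under each alternative was not counted.

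Among all 13513 probe sets with 1 gene, 101 matched the pattern, which is not the number of transcription factors. The odds ratio of enrichment of matching genes was 1.44 (95% interval 0.603 to 2.98) in phloem, 0.995 (0.315 to 2.42) in cortex and 1.36 (0.531 to 2.93) in xylem. Fisher's exact test gave adjusted p = 0.554, 1 and 0.554, so no difference from genes that did not match was detectable, and factors that the pattern missed count among the latter.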

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

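Scaling on spike-in controls or on the trimmed mean was added after seeing the data, and the other alternatives were fixed beforehand. The counts for xylem against cortex and xylem against phloem stayed within 1.5 times 9696 and 9639 under the alternatives run, at 7602 to 13793 and 7101 to 13069. The odds ratios of genes matching the transcription factor pattern did not pass under any of them, and the phloem list for phloem against cortex passed under all. For phloem against cortex the count was 9895 after spike-in scaling and ranged from 3606 (without phloem replicate 2) to 7489 (without xylem replicate 2) when arrays were left out. The lone phloem array left there was assumed to vary like the other groups. Enriched probe sets in xylem numbered 2391 after median centring and 798 after spike-in scaling, and those in cortex 3870 after spike-in scaling. By construction, no fold minimum gave 2191 in cortex and 2025 in xylem, and a 4-fold minimum gave 630 in phloem, 334 in cortex and 556 in xylem. For gene lists, some calls were lost under an estimated correlation, with their mean log2 fold changes unchanged. For xylem against cortex these means were 2.85 (auxin), -3.91 (cortex) and 5.86 (secondary wall). They were 1.14 (auxin) and -3.31 (cortex) for phloem against cortex, and -2.998 (phloem) and 6.21 (secondary wall) for xylem against phloem. With the estimate camera also takes the 5 residual degrees of freedom of the fit in place of a number based on all probe sets. For the phloem list the estimated correlation was -0.067, under the preset one, so a higher correlation did not end its call. For the auxin, cortex and secondary wall lists the estimate lay above the preset one. Which change ended the calls of these lists was not tested. The auxin call for phloem against cortex was also lost with pseudocount 64 (0.52) and quantile normalization (0.93). The auxin list passed for xylem against phloem after spike-in scaling (1.54) and without phloem replicate 2 (range over left-out arrays 1.58 to 1.83). Of 300 comparisons of named genes 236 passed, and 195 of these held with the same sign under all alternatives. Comparisons with both other populations were judged here on adjusted p, without the 2-fold minimum. The 3 that reversed had not passed: RR16 for xylem against phloem after median centring (0.44), and AT4G34270 (-0.80) and AT2G28390 (-0.73) for xylem against cortex after spike-in scaling. For these and the lost calls under other scalings the cause was not tested. With the replicate block the counts were 9557, 5579 and 9114, and 1412, 1400 and 1263 were enriched in phloem, cortex and xylem; no list call changed, and among named-gene comparisons 4 calls were lost and 1 was gained. Signal over background is not known without detection calls; between 22.3% and 30.8% of probe sets lay under an intensity of 16.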

Other observations

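The families below were formed from shared symbol prefixes after the data were seen, 47 families with at least 5 members. Not all that passed are described: ALDH, IAA and NAD, among others, also passed camera in a pair at the preset correlation. For the patterns that follow, the tests of array scaling and of dim probe sets for the balance of higher and lower calls, the comparison with mitochondrial probe sets, and the heat-shock tests of noise and of other cells were chosen after the result was seen.

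Of 47 genes for UDP-glycosyltransferases (UGT), which attach sugars to small molecules, 15 were cortex-enriched (odds ratio 9.14, Fisher's exact test adjusted p = 2.89e-07 over 141 tests), and 13 to 23 were under the 4 other scalings. Under those scalings the odds ratio ranged from 5.80 (spike-in, with the 23 genes) to 9.03 (trimmed mean). Without phloem replicate 2 the number was 8 (odds ratio 5.65), with 1 phloem array left. Fisher's test treats genes as independent. With camera the family was lower in xylem and in phloem than in cortex, adjusted p = 0.0137 and 0.0109, and both calls were lost, adjusted p = 0.541 and 0.303 with an estimated correlation. Their median log2 fold change was -1.18 for xylem against cortex (-1.70 to -0.75 under the other scalings) and -0.61 for phloem against cortex (-1.04 to -0.50), and relative to the median of all probe sets -1.04 (-1.04 to -0.88) and -0.59 (-0.60 to -0.53). UGT72E2 and UGT72E3, glucosyltransferases of lignin precursors, were lower in xylem than in cortex at -4.45 and -2.51. UGT74F1 and UGT87A2 were xylem-enriched instead, at 5.37 and 3.04 against cortex. Of 26 cytochrome P450 genes 6 were cortex-enriched, among them CYP84A4 and CYP71B6, a share that did not pass (adjusted p = 0.0681).

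Neither the SWEET sugar transporters nor the CLE signal peptides passed Fisher's test of enrichment in phloem over 141 tests. Of 14 SWEET genes 4 were phloem-enriched (adjusted p = 0.15): SWEET11, SWEET3, SWEET14 and SWEET8, at 4.204, 3.34, 2.71 and 1.25 against cortex. Against cortex 5 SWEET genes were higher in phloem and 3 lower, SWEET16, SWEET17 and SWEET2 at -2.35, -1.99 and -1.12. Without phloem replicate 1, phloem replicate 2 or cortex replicate 2 these numbers were 3 and 2, and after spike-in scaling both were 3. The family median was -0.0042 (camera adjusted p = 0.544). Of 6 CLE genes 3 were phloem-enriched (adjusted p = 0.111): CLE26, CLE41 and CLE44, at 5.27, 2.84 and 1.10. The CLE family passed with camera against cortex, adjusted p = 0.0183, and the call was lost, adjusted p = 0.303 with an estimated correlation. Autophagy genes of the ATG prefix were higher in phloem than in cortex in 5 of 8 (median 1.07, and 0.44 to 1.20 under the other scalings), led by ATG8B at 3.29 and ATG8D at 3.06, and in 3 of 8 without phloem replicate 2 or after spike-in scaling, with a camera adjusted p of 0.00186 and adjusted p = 0.303 with an estimated correlation. Xylem also exceeded cortex in 5 of 8 ATG genes (median 0.54, and -0.30 to 0.98 under the other scalings), and 2 of 8 were phloem-enriched. For xylem against phloem their median was -0.50 (camera adjusted p = 0.568). The SEC prefix, mostly subunits of the exocyst that tethers secretory vesicles, was higher in xylem than in phloem in 7 of 8 (median 1.23, and 1.03 to 1.83 under the other scalings), led by SEC10 at 2.33 and SEC15B at 1.99. The camera adjusted p was 0.000407, and adjusted p = 0.511 with an estimated correlation. Against cortex 6 of 8 were higher in xylem (median 0.95, and 0.23 to 1.39 under the other scalings). After spike-in scaling 2 were higher and 1 lower. The camera adjusted p there was 0.00391, and adjusted p = 0.541 with an estimated correlation, both with the arrays as deposited.

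Of 69 plastid-encoded probe sets, 33 were higher in phloem than in cortex and 45 lower in xylem than in cortex (medians 0.77 and -1.10), for example rps4 at 1.29 and -2.22. The camera adjusted p was 8.69e-10 and 2.86e-06, and both calls were lost, adjusted p = 0.303 and 0.548 with an estimated correlation. Under the 4 other scalings the xylem median stayed at or under -0.67, which argues against array scaling as its whole cause. The phloem median came to 0.25 under spike-in scaling, short of the bound of 0.3 set for excluding array scaling. Under that scaling 19 were higher and 7 lower in phloem than in cortex, and relative to all probe sets the median was 0.68. Mitochondrial probe sets (23) were taken per array, since probe sets of one genome are not independent: the plastid minus the mitochondrial median deviation was -0.56 ± 0.55 in xylem (n = 3; -1.19 in replicate 2) and 0.61 ± 0.12 in cortex (n = 3), a difference of -1.17 with every xylem array under every cortex array (exact permutation p = 0.1, the smallest possible), which argues against 1 equal shift of all organelle RNA. For phloem against cortex that difference was 0.11 with overlapping arrays (2-sided exact permutation p = 0.5), so a common gain of organelle RNA, which may reflect amplification of such RNA or the cells themselves, stays open there, and for xylem a difference in plastids between cell types stays an untested hypothesis.

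Of 17 listed small heat-shock protein genes 8 were measured, and their median was 10.28 and 10.12 in xylem replicates 1 and 3, 6.46 in xylem replicate 2 and 6.71 to 7.66 in the phloem and cortex arrays, so that 7 instead of 2 were higher in xylem than in cortex without xylem replicate 2. The list was put together after the low genes of replicate 2 were seen, so its median deviation there of -3.37, against -1.31 for the lowest of 10000 random lists, cannot argue against noise in that array, where 230 probe sets lay at least 4-fold from the mean of replicates 1 and 3, against 11 between those. Cells of another population in replicate 2 would have diluted xylem genes, yet xylem-enriched probe sets moved by a median of -0.026, and phloem-enriched and cortex-enriched ones by 0.0019 and -0.14. The GAPDH and actin 3'/5' ratios were the highest of the 8 arrays in replicate 2, while its ubiquitin ratio of 2.10 was highest within xylem alone. The deviation did not fall with gene length (Spearman 0.035 across 6010 probe sets, which are not independent replicates). Gene length does not give the distance of the probes from the 3' end, so this cannot exclude loss of 5' signal. Noise, loss of 5' signal, a difference in handling, or a heat or stress response in replicates 1 and 3, may remain. Neither handling nor such a response was tested, since the labels give no batch and no biological difference between replicates.

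More probe sets were lower than higher in xylem than in cortex. Median centring and quantile normalization set the centre of each array and with it this balance by construction (63.8% and 48.9% higher), while trimmed-mean scaling gave 40.2% and spike-in scaling 11.1%, against 31.7% as deposited, so the scaling moves the balance either way and may or may not have caused it. Among probe sets above the median intensity the share was 33.9%, so the imbalance was not confined to the dimmer probe sets. A probe set can lie above that median through the other populations and still be dim in xylem. This share therefore cannot exclude dim signal in xylem as a source of the imbalance. Scaling and a real difference in total or diverse mRNA between cell types cannot be told apart, because the files fix no absolute level. For the number called between xylem and cortex, the 6 arrays allow 10 splits, of which 1, the real one, gave as many as 9696, and the highest of the others gave 0 with limma (736 at an unadjusted p under 0.05). With 10 splits no share under 0.05 can be reached. Every other split also mixes xylem and cortex arrays on each side. Their difference then enters the spread, so few calls there could be foreseen and do not measure chance.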
